A study of Caenorhabditis elegans with 36 samples.

How the data were processed

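Gene expression was measured by RNA sequencing in whole Caenorhabditis elegans of the wild-type strain N2. The animals received RNAi with the empty vector L4440, or against prp-19 or skp-1, and were collected at 1, 5, 10 or 15 days. The 36 libraries form 12 groups of 3. Per the labels the material was total RNA and the kit was TruSeq Stranded mRNA. The labels do not say whether the 3 libraries of a group came from separate cultures, whether progeny were removed or prevented, or when RNAi began. The 9 libraries with a 15 day age label also carry a source name of 10 days. They were analysed as 15 days, and the counts of genes of comparisons that do not use day 15 were recomputed without them as an alternative. Replicate numbers were assigned here in the order of the sample list, because the labels give none.

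The deposited counts file holds the count of reads per gene (unit: count) for 46748 genes. Per the processing notes, the authors demultiplexed with bcl2fastq 1.8.4, aligned reads to WBcel235 with STAR 2.4.1d and counted them with featureCounts 1.4.6-p4. The strand setting of the counting is not given in the sources used here. The deposited RPKM file holds a score per gene, named RPKM (reads scaled by transcript length and library total) by the authors. Checked against the counts, that file was made by dividing each value by a library total that runs on down the table with a period of 36 values. Most values were therefore divided by the total of another library. Over 7400 genes the gene length recovered with the running total had a coefficient of variation of 0.00124%, and with each library's own total it was 21.9%. The value matched its own total for 2.8% of values, and the wrong total moved a value by up to 1.99-fold. The counts were used for every result, and the RPKM file only for an alternative.

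Total counts ran from 22689243 to 45091100 per library. A count of 3, used as the floor for a gene not seen, corresponded to between 0.0665 and 0.132 CPM (counts scaled to a total of 1e6). Libraries of 1 group differed by more than sampling noise, with chi-squared per degree of freedom from 18.88 to 436.17 between pairs, and 0 pairs were identical. Reads were not tagged with molecular identifiers, so intervals and floors cover counting error only. Of the 46748 genes, 16335 had a count of 0 in all libraries, 43693 had a gene name and 46449 were in the annotation used here (Ensembl release 115, WBcel235).

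Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, the filter filterByExpr with its defaults, and a quasi-likelihood model with robust dispersion and 1 mean per group over all 36 libraries. The filter left 18856 genes. The biological coefficient of variation was 0.251, with 24 residual degrees of freedom and a median of 4.76 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p of 0.05. Log2 fold changes are given with their standard error (SE), and CPM values as the mean and standard deviation (SD) of 3 libraries. Each RNAi was compared with L4440 at each age and averaged over the 4 ages, and its interaction with age was tested. The RNAis were compared with each other at each age. The L4440 ages were compared as 5, 10 and 15 days with 1 day, 10 with 5 and 15 with 10. The p-values measure only the spread between these samples.

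Lists of genes were tested with camera from limma 3.58.1 with its preset correlation of 0.01, adjusted over 30 lists in each comparison, and again with a correlation estimated per list. The lists covered the spliceosome core, splicing regulators, nonsense-mediated decay, vitellogenins, sperm genes, germline and meiosis, oocyte and eggshell, early zygotic embryo, larval molting, DNA replication and cell division, DNA damage and apoptosis, histones, ribosomal proteins, the proteasome, oxidative phosphorylation, cytosolic heat shock, the mitochondrial and the endoplasmic reticulum unfolded protein responses, detoxification, DAF-16 targets, intestinal innate immunity, epidermal antimicrobial peptides, the intracellular pathogen response, cuticle collagens, body wall muscle and pharynx, neurons, intestine, lipid metabolism, autophagy and lysosome, and the RNA interference machinery. They were written from general knowledge, and none was chosen on these samples. List counts are given over all tested genes and, where they differ, "adjusted over the list alone". Counts, comparisons, lists, the rule for named genes and most alternatives to try were fixed before the data were examined.

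The rule for named genes took prp-19 and skp-1 and, in each comparison of an RNAi with L4440 and of L4440 at 5, 10 or 15 days with 1 day, the 5 largest rises and 5 largest falls. These had to be called, to reach 10 CPM in the higher group, to have a gene name and to have all 3 libraries of 1 group above all 3 of the other, which chance gives for 10% of genes. For each list it took up to 2 risen and 2 fallen genes with the smallest adjusted p and at least 5 CPM. For the averages it took 5 genes each way, and for the interactions the 10 smallest adjusted p. A gene outside the rule is named as such.

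Alternatives fixed in advance were RLE size factors, TMM without the 20 most abundant genes, DESeq2 1.42.0, no filter on low counts, a filter of at least 5 CPM in 3 libraries, dispersions without the robust option, a fit of only the groups compared, the data without the 9 libraries of conflicting age, the authors' RPKM values with limma-trend and a pseudocount of 0.1 or 1, each library left out in turn, and the estimated correlation for lists. Chosen after seeing the data were a fit without the 2 libraries with an rRNA share above 10%, RPKM values recomputed with each library's own total and a replicate block from the order of the sample list. For each comparison of 3 with 3 libraries the 10 splits of the 6 libraries were refitted. For the averages and interactions, 50 splits within ages were drawn. The overlap between the RNAis was set beside 20 simulations per age in which they shared control libraries but no effect, with controls drawn from the same model as the RNAi libraries.

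The pipeline was tested on simulated data in which 100 genes were changed by each fold. With edgeR, 64% of 2-fold and 92% of 4-fold changes were called for prp-19 RNAi at day 1, with 4 other genes called. At day 5 the shares were 66% and 92%, with 5 others. For the average over ages they were 62% and 91%, with 2 others, and for the interaction 57% and 87%, with 4 others. At day 5, limma-trend called 66% and 90%, with 10 others, and DESeq2 75% and 96%, with 21 others. With no gene changed, edgeR called 0 genes in each of 4 simulations. A shifted proteasome list was recovered by camera at an adjusted p of 1.7e-59 with no other list called, and without a shift 0 lists were called.

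Intervals of medians came from 2000 bootstrap draws over genes at 95% confidence, and permutation tests across genes from 9999 permutations. These intervals leave out the spread between libraries. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Sequence reads were not used here, so splicing of individual introns was not measured. Genes of families with near-identical members, such as fbxb, msp, vit, col and hsp-16, share reads that the counting may have assigned to another member or dropped.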

Results

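RNA was sequenced from whole hermaphrodite nematodes of the C. elegans strain N2 after RNAi against prp-19 or skp-1, or with the empty vector L4440, the control. The gene prp-19 encodes the namesake core member of the Prp19 complex of the spliceosome, and skp-1 encodes the worm homologue of SKIP, a splicing and transcription cofactor that joins the same activated spliceosome. The series covers 4 ages (1, 5, 10 and 15 days) and 3 RNAi conditions, with 3 libraries in each of 12 groups. Total counts per library ran from 22689243 to 45091100 reads on genes, and 18856 genes were tested. On a plot of distances between libraries built from 1000 genes, the first 3 axes held 59.3%, 14.5% and 7.3% of the variance. Below, gene changes are log2 fold changes ± SE from the edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p, levels are CPM as mean ± SD, and n = 3 libraries per group. Ribosomal RNA took 16.77% of counts in L4440 day 10 replicate 2 (1.1% in the lowest library of that group) and 11.52% in prp-19 day 10 replicate 3 (2.07% in the lowest).

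The first question was whether each targeted transcript was lower in its own libraries, and at which ages. The prp-19 transcript (WBGene00020423, WBcel235 chromosome III, 5169933 to 5172045, minus strand, 4 exons) was at 20.2% of L4440 after prp-19 RNAi at day 1, 67.4 ± 7.75 against 333 ± 6.87 CPM (log2 fold change -2.31 ± 0.36, adjusted p = 0.00048). At day 5 it was at 23% (-2.12 ± 0.35, adjusted p = 5.2e-06). In the libraries labelled prp-19 RNAi it was not lower at day 10, 459 ± 306 against 321 ± 16.8 CPM (0.52 ± 0.34, adjusted p = 0.19; 1.00, adjusted p = 0.0067, without prp-19 day 10 replicate 2 and -0.11, adjusted p = 0.78, without replicate 3), with 419, 175 and 783 CPM in replicates 1 to 3 at rRNA shares of 6.54%, 2.07% and 11.52%, nor at day 15, 253 ± 154 against 283 ± 31.4 CPM (-0.16 ± 0.34, adjusted p = 0.69; -0.71, adjusted p = 0.068, without prp-19 day 15 replicate 2, the highest at 430 CPM). The skp-1 transcript (WBGene00004806, chromosome V, 11645481 to 11650090, plus strand, 6 exons) was at 26.7% of L4440 after skp-1 RNAi at day 1, 59.4 ± 9.86 against 222 ± 46.3 CPM (-1.90 ± 0.40, adjusted p = 0.0022). At day 5 it was at 33.5% (-1.58 ± 0.39, adjusted p = 0.00078), and at day 10 it did not differ from L4440 by the test (0.03 ± 0.38, adjusted p = 0.95). At day 15 it was higher in the libraries labelled skp-1 RNAi, 701 ± 676 against 195 ± 28 CPM (1.85 ± 0.40, adjusted p = 0.00015), which rests largely on skp-1 day 15 replicate 3 at 1470 CPM (0.69, adjusted p = 0.028, without it). Reads from an RNAi trigger cannot be separated here from those of the transcript. Whether labels of the older libraries were exchanged was not tested, and zip-10 overlaps the 3′ end of skp-1 on the opposite strand.

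Each targeted transcript was also measured under the other RNAi. At day 1, skp-1 was at 222 ± 21.9 CPM after prp-19 RNAi (0.00 ± 0.38, adjusted p = 1) and prp-19 at 410 ± 25 CPM after skp-1 RNAi (0.30 ± 0.34, adjusted p = 0.98). At day 5, skp-1 fell after prp-19 RNAi to 37.9% of L4440 (-1.40 ± 0.39, adjusted p = 0.0021) and did not pass the test at day 10 (adjusted p = 0.61) or 15 (0.96). Its fall at day 5 was close to that under its own RNAi (33.5%, -1.58 ± 0.39), so it was not particular to skp-1 RNAi. The prp-19 transcript fell in skp-1 RNAi libraries at day 5 to 176 ± 19.8 CPM (-1.09 ± 0.34, adjusted p = 0.0057). It was also lower in those labelled skp-1 RNAi at day 10 (-1.31 ± 0.35, adjusted p = 0.0013) and day 15 (-1.79 ± 0.35, adjusted p = 4.5e-05), ages at which skp-1 itself was not lower.

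**Figure D1:**
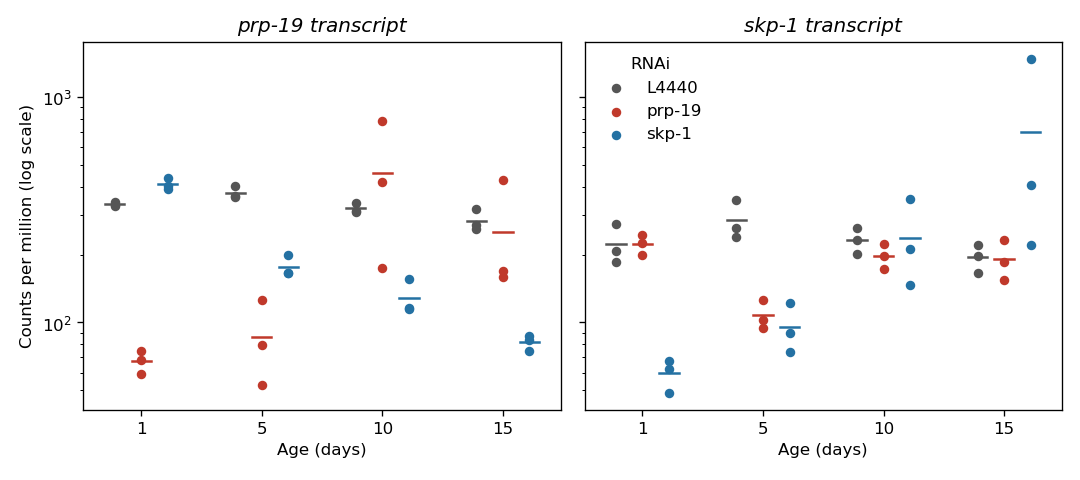
CPM (log axis) of prp-19 and skp-1 in each library by age in days and RNAi condition; points are libraries and bars are means of 3. By the edgeR test each target was lower than in L4440 in its own RNAi at days 1 and 5, and not at days 10 and 15. At day 5 each was also lower under the other RNAi.

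At day 1, prp-19 RNAi left most genes near their L4440 level and raised a small set of splicing genes. The splicing factor gene dib-1, homologue of a component of the tri-snRNP, rose 2-fold, 194 ± 18 against 96.9 ± 9.3 CPM (1.00 ± 0.12, adjusted p = 1.9e-05). The Sm protein gene snr-6 rose by 0.68 ± 0.12 (adjusted p = 0.0021). tos-1, an RNA-binding protein gene known as a splicing reporter, rose 1.94-fold (0.96 ± 0.15, adjusted p = 0.00048). The BTB-domain gene btb-11 fell to 2.18 ± 0.242 from 15.6 ± 3.8 CPM (-2.84 ± 0.28, adjusted p = 1.2e-06). The sdz genes sdz-28 (-2.07 ± 0.31, adjusted p = 0.00033) and sdz-30 (-1.84 ± 0.25, adjusted p = 0.00012), named for zygotic expression that needs SKN-1, fell as well. The largest rise under the rule for named genes was of the noncoding RNA gene tts-1, 162 ± 48.7 against 58.8 ± 11.7 CPM (1.46 ± 0.37, adjusted p = 0.036). That call ended without any of L4440 day 1 replicates 1 (adjusted p = 0.14), 2 (0.14) and 3 (0.12), prp-19 day 1 replicates 2 (0.26) and 3 (0.12) or L4440 day 10 replicate 1 (0.05). A replicate block from the order of the sample list ended it as well.

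Of the 55 spliceosome core genes tested at day 1 after prp-19 RNAi, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with a list median of 0.16 (camera adjusted p = 1.5e-10; adjusted p = 0.79 with an estimated correlation). Among 36 larval molting genes 0 rose and 2 fell (0 and 14 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 1.3e-06; adjusted p = 0.79 with an estimated correlation). The list level in L4440 was 2.03, 0.94 and 1.99 log2 CPM in replicates 1 to 3, so replicate 2 lay below the prp-19 RNAi libraries (each 1.1 after rounding), and the median was -0.30 without L4440 day 1 replicate 3 and -0.89 without replicate 2. Of 163 cuticle collagens 2 rose and 7 fell, and the list median was -0.41, or -0.36 with 7 genes of count 0 at their bound. The early zygotic list had 1 fallen gene (3 adjusted over the list alone) and the intestinal innate immunity list 1 risen gene. In all, 236 genes were called, 60 higher and 176 lower, beside 1438 at an unadjusted p under 0.05 and 335 by DESeq2. The count was 61 without L4440 day 1 replicate 1, 360 without L4440 day 1 replicate 2, 91 without prp-19 day 1 replicate 2 and 92 without prp-19 day 1 replicate 3. It was 21 with only the groups compared, 107 with at least 5 CPM, and 49 and 29 with the authors' RPKM values. The split by direction moved too. It was 26 higher and 35 lower without L4440 day 1 replicate 1 and 46 and 314 without L4440 day 1 replicate 2. With only the groups compared it was 11 and 10, and with the authors' RPKM values at a pseudocount of 0.1 it was 14 and 15.

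After skp-1 RNAi at day 1, a part of the early zygotic and larval molting genes fell and a few splicing genes rose. dib-1 rose by 0.95 ± 0.12 (adjusted p = 1.9e-06), tos-1 by 0.95 ± 0.15 (adjusted p = 4.3e-05), snr-6 by 0.66 ± 0.12 (adjusted p = 0.00047) and plrg-1, homologue of a Prp19 complex member, by 0.57 ± 0.12 (adjusted p = 0.0026). In the germline, fog-2, an F-box gene of hermaphrodite sperm specification, rose by 0.73 ± 0.15 (adjusted p = 0.0014). The hatching protease gene hch-1 was at 0.0584 ± 0.101 against 13.3 ± 14.9 CPM (-7.59 ± 1.03, adjusted p = 8.3e-06), and dpy-14, an embryonic cuticle collagen, at 0.331 ± 0.3 against 28.4 ± 29.2 CPM (-6.35 ± 0.79, adjusted p = 2.5e-06). Other large falls were those of arrd-1, an arrestin domain gene (-5.11 ± 0.41, adjusted p = 3.3e-09), the lectin gene clec-196 (-5.01 ± 0.50, adjusted p = 5.1e-08) and sym-1 (-4.67 ± 0.63, adjusted p = 8e-06). The L4440 day 1 libraries spread widely for several of these genes, as the SDs of hch-1 and dpy-14 show.

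The early zygotic embryo list had 13 fallen and 0 risen genes of 33 (16 and 2 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.7e-13; adjusted p = 0.18 with an estimated correlation). In it, sdz-28 was 15.9-fold lower (-3.99 ± 0.34, adjusted p = 4.6e-09) and dsl-2, of the Notch ligand family, 5.42-fold lower. Larval molting genes fell in 11 of 36 cases with 0 rises (14 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 4e-07; adjusted p = 0.37 with an estimated correlation). Examples are fbn-1, which encodes a fibrillin-like matrix protein (-4.51 ± 0.64), and the hedgehog-related wrt-10 (-4.24 ± 0.57). Of 55 spliceosome core genes 6 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 7.6e-07; adjusted p = 0.98 with an estimated correlation). Among 163 collagens 2 rose and 10 fell, and among 34 oocyte and eggshell genes 0 were called. In all 895 genes were called, 199 higher and 696 lower, and 2049 had an unadjusted p under 0.05. The count was 547 without L4440 day 1 replicate 1, 428 with at least 5 CPM, 439 with only the groups compared, and 570 with the authors' RPKM values at a pseudocount of 0.1.

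Compared directly at day 1, prp-19 RNAi had higher early zygotic expression than skp-1 RNAi. In that list 9 genes were higher and 1 lower (15 and 1 adjusted over the list alone), with a median difference of 0.72 (camera adjusted p = 1.6e-25; adjusted p = 0.0094 with an estimated correlation). Across every comparison tested with the lists, this call and that of the muscle list in L4440 at day 5 against day 1 were the only list calls that held with an estimated correlation. In all 247 genes differed, 208 higher and 39 lower after prp-19 RNAi. The count was 128 without prp-19 day 1 replicate 1, 150 without skp-1 day 1 replicate 3, 118 with at least 5 CPM and 87 with only the groups compared.

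A class of genes outside the lists, chosen after its values were seen, was noncoding genes that lie inside introns of coding genes. At day 1 their median log2 fold change was 0.64 over 210 genes after prp-19 RNAi and 1.1 after skp-1 RNAi, beside 0.22 and 0.30 over 257 noncoding genes outside coding genes. The difference of medians was 0.42 (95% bootstrap interval 0.21 to 0.62) and 0.80 (0.52 to 1.11). Of the 210 genes 2 passed the edgeR test as higher after prp-19 RNAi and 30 after skp-1 RNAi, with 0 lower, and of the 257 genes 3 and 40 did, with 1 and 3 lower, so the called shares inside and outside introns were alike.

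**Figure D2:**
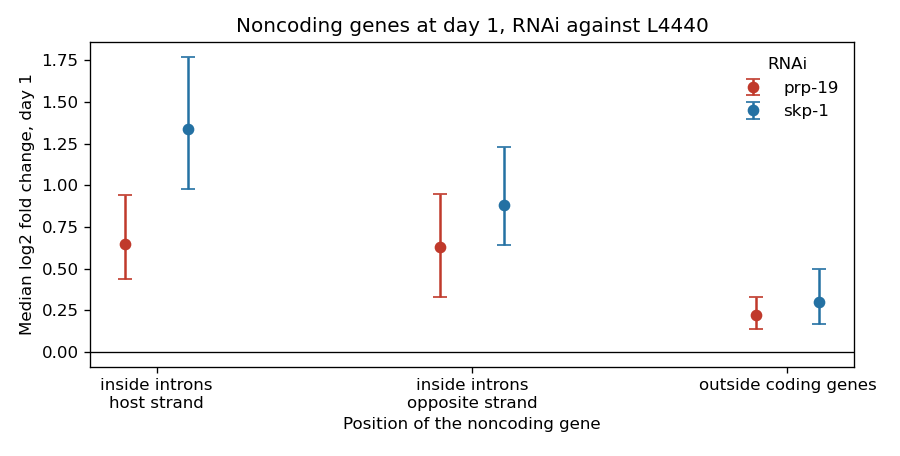
Median log2 fold change at day 1, RNAi against L4440, of noncoding genes inside introns on the host strand, inside introns on the opposite strand and outside coding genes; bars are 95% bootstrap intervals over genes. Medians inside introns on the host strand were 0.65 for prp-19 and 1.34 for skp-1.

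By day 5 both RNAis had lower oocyte, germline and cell division transcripts and higher neuronal, muscle and pathogen response transcripts than L4440. Changes were widespread, with 9627 of 18856 tested genes higher and 5734 lower after prp-19 RNAi, and 8385 and 5681 after skp-1 RNAi. The median of all genes was 0.95 and 0.65, so list counts and medians at this age stand against that background. The libraries are of whole worms. Here and at the later ages, a changed share of germline RNA cannot be told apart from changed expression within tissues. After prp-19 RNAi, chs-1, the chitin synthase of the eggshell, was 13.5-fold lower, 43.1 ± 2.47 against 583 ± 27.4 CPM (-3.76 ± 0.20, adjusted p = 5.1e-15). After skp-1 RNAi it was 22.3-fold lower (-4.48 ± 0.21, adjusted p = 7.4e-16). Of 34 oocyte and eggshell genes 32 fell and 2 rose after either RNAi, with medians of -3.21 (camera adjusted p = 2.9e-19; adjusted p = 0.14 with an estimated correlation) and -3.20 (8e-21; 0.14). Both lists of risen genes held perm-4, an eggshell permeability gene (2.12 ± 0.33 after prp-19 RNAi). In the germline and meiosis list 45 of 48 genes fell and 2 rose after either RNAi, with medians of -2.38 (camera adjusted p = 3.9e-17; adjusted p = 0.14 with an estimated correlation) and -2.14 (2.8e-16; 0.19). There car-1, a germline RNA-binding protein gene, was 9.64-fold lower after prp-19 RNAi and 9.08-fold lower after skp-1 RNAi. All 50 replication and cell division genes fell after each RNAi, with medians of -2.57 (camera adjusted p = 1.5e-29; adjusted p = 0.14 with an estimated correlation) and -2.1 (3.7e-24; 0.14). The meiotic kinesin gene klp-15 was 10.9-fold and 14.2-fold lower, respectively.

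Splicing genes were lower at day 5. In the spliceosome core 48 of 55 genes fell and 0 rose after prp-19 RNAi, with a median of -1 (camera adjusted p = 3e-08; adjusted p = 0.26 with an estimated correlation). After skp-1 RNAi 38 fell and 1 rose, with a median of -0.71 (1.1e-05; adjusted p = 0.40 with an estimated correlation). The spliceosome gene syf-2 fell to 42 ± 1.45 from 136 ± 3.96 CPM after prp-19 RNAi (-1.70 ± 0.10, adjusted p = 2.4e-14) and by 1.73 ± 0.10 after skp-1 RNAi. Of 38 splicing regulators 30 fell and 7 rose, and 29 fell and 7 rose. The hnRNP K homologue hrpk-1 was 6.16-fold and 6.58-fold lower, while mbl-1, the muscleblind homologue, rose 4.57-fold after skp-1 RNAi. Nonsense-mediated decay genes fell in 10 of 11 cases with 0 rises after either RNAi, smg-4 by 1.64 ± 0.12 after prp-19 RNAi. Of 77 ribosomal protein genes 68 fell and 4 rose after prp-19 RNAi (median -0.93) and 70 fell and 2 rose after skp-1 RNAi (median -0.76). Proteasome genes fell in 33 of 35 cases with 1 rise, and in 35 of 35, rpt-1 by 1.59 ± 0.11 after prp-19 RNAi. Oxidative phosphorylation genes fell in 41 of 49 cases with 2 rises, and in 40 with 4 rises (41 and 4 adjusted over the list alone).

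Small RNA pathway genes were among those lower at day 5. In the RNA interference list 41 of 53 genes fell and 8 rose after prp-19 RNAi, and 40 fell and 6 rose after skp-1 RNAi. The nuclear Argonaute gene hrde-1 was 7.69-fold and 8.34-fold lower. The DNA damage and apoptosis list had 29 fallen genes of 35 after either RNAi, with 5 and 4 risen, among them egl-1, a trigger of apoptosis (2.42 ± 0.48, adjusted p = 5.1e-05, after prp-19 RNAi and 3.20 ± 0.49, adjusted p = 1.4e-06, after skp-1 RNAi). Histone genes fell in 23 and 22 of 39 cases and rose in 8 and 6. Of 20 mitochondrial unfolded protein response genes 15 fell and 3 rose after either RNAi.

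Other lists moved up at day 5. Of 71 neuronal genes 65 rose and 4 fell after prp-19 RNAi (66 and 4 adjusted over the list alone), with a median of 1.72 (camera adjusted p = 1.3e-07; adjusted p = 0.36 with an estimated correlation). After skp-1 RNAi 66 rose and 3 fell, with the same median (9e-08; adjusted p = 0.38 with an estimated correlation). The syntaxin gene unc-64 rose 3.54-fold after skp-1 RNAi, and tdc-1, the tyrosine decarboxylase of a few neurons and of gonadal sheath cells, fell by 3.60 ± 0.20 after prp-19 RNAi and was 11.4-fold lower after skp-1 RNAi. In the muscle list 43 of 50 genes rose and 3 fell after either RNAi, the integrin gene pat-2 5.84-fold after prp-19 RNAi. The mean level of that list was 5.44 ± 0.26 log2 CPM in L4440 at day 5, below 6.65 ± 0.21 at day 1, and 6.73 ± 0.17 and 6.66 ± 0.10 after the RNAis at day 5. The intracellular pathogen response list, genes induced by viruses and microsporidia, had 56 risen and 1 fallen of 60 after prp-19 RNAi (57 and 1 adjusted over the list alone), with a median of 2.19, or 2.15 with 2 genes of count 0 at their bound (camera adjusted p = 1.8e-07; adjusted p = 0.18 with an estimated correlation). After skp-1 RNAi 47 rose and 1 fell (48 and 1 adjusted over the list alone). Its cullin gene cul-6 rose 7.35-fold (2.88 ± 0.15, adjusted p = 5.5e-15) and 9.29-fold (3.22 ± 0.16, adjusted p = 1.7e-15). Detoxification genes rose in 38 of 64 cases with 6 falls (38 and 5 adjusted over the list alone), and in 41 with 4 falls. The glucuronosyltransferase gene ugt-25 rose 20-fold after skp-1 RNAi and gst-24 7.55-fold after prp-19 RNAi. By contrast fmo-2, a flavin monooxygenase gene of the innate immunity list, was 52.9-fold and 49.4-fold lower than in L4440. In L4440 itself fmo-2 had risen 57.6-fold, from 1.07 ± 0.585 CPM at day 1 to 62.8 ± 31.2 CPM at day 5.

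Sperm genes set the RNAis apart at day 5. Of 53 sperm genes 42 rose and 2 fell after prp-19 RNAi (43 and 2 adjusted over the list alone), with a median of 1.90 (camera adjusted p = 0.032; adjusted p = 0.89 with an estimated correlation), and 3 rose and 2 fell after skp-1 RNAi, with a median of -0.40. The L4440 libraries spread widely for this list, at -1.27, 1.44 and -0.05 log2 CPM in replicates 1 to 3, all below the prp-19 RNAi libraries (1.81 to 2.73). The median after prp-19 RNAi was 3.12 without L4440 day 5 replicate 2, and the call ended without L4440 day 5 replicate 1 (1.29, adjusted p = 0.061) or prp-19 day 5 replicate 3 (1.41, adjusted p = 0.088). Compared directly, 32 were higher after prp-19 RNAi and 0 lower (47 and 0 adjusted over the list alone), with a median difference of 2.25 (camera adjusted p = 9.8e-17; adjusted p = 0.77 with an estimated correlation). The sperm membrane gene fer-1 rose 14.1-fold after prp-19 RNAi and 10.1-fold after skp-1 RNAi. Vitellogenins, the yolk protein genes, were higher than in L4440 in 4 of 6 cases and lower in 0 after either RNAi (2 higher adjusted over the list alone for prp-19). The gene vit-3 was at 2010 ± 1080 against 621 ± 41.5 CPM after prp-19 RNAi. Part of this difference is a fall in the control. The list mean in L4440 was 13.24 ± 0.22 log2 CPM at day 1 and 11.62 ± 0.11 at day 5. At day 5 it was 12.77 ± 0.51 after prp-19 RNAi and 12.79 ± 0.27 after skp-1 RNAi.

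The remaining lists split at day 5. Epidermal antimicrobial peptide genes rose in 27 of 41 cases after prp-19 RNAi and in 28 after skp-1 RNAi, with 0 falls. Of 71 intestinal innate immunity genes 28 rose and 4 fell, and 34 rose and 3 fell (26 and 3, and 33 and 3, adjusted over the list alone), and in that list the antibacterial peptide gene abf-2 rose 7.58-fold after skp-1 RNAi. DAF-16 target and antioxidant genes rose in 18 and 19 of 31 cases and fell in 7 each time. Of 23 heat shock genes 12 rose and 8 fell after prp-19 RNAi, and 7 rose and 11 fell after skp-1 RNAi. In that list sip-1, a small heat shock protein gene of embryos, was 9.35-fold and 11.7-fold lower. The small heat shock gene hsp-16.48 was among the 5 largest rises after prp-19 RNAi, from 3.47 ± 1.04 CPM (5.01 ± 0.61). Endoplasmic reticulum stress genes (26) rose in 5 cases and fell in 11, and rose in 7 and fell in 8. Intestine genes (37) rose in 15 and fell in 4, and rose in 20 and fell in 4. Lipid metabolism genes (82) rose in 34 and fell in 20, and rose in 42 and fell in 14; dgat-2, of triglyceride synthesis, rose 11.5-fold and 16.7-fold. Autophagy and lysosome genes (60) rose in 20 and fell in 19, and rose in 30 and fell in 16, with the receptor gene sqst-1 4.48-fold higher after prp-19 RNAi. Early zygotic genes (33) rose in 15 and fell in 14 after either RNAi. Larval molting genes (36) rose in 13 and fell in 9 (11 and 8 adjusted over the list alone), and rose in 8 and fell in 20. Collagens rose in 41 and fell in 71 of 163 cases (41 and 68 adjusted over the list alone), and rose in 30 and fell in 90.

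Beyond the lists, the guanylyl cyclase gene gcy-34 rose from 0.177 ± 0.0249 to 16 ± 1.13 CPM after prp-19 RNAi (6.47 ± 0.53, adjusted p = 1.3e-11), and skr-9, a Skp1-related gene, fell from 99.3 ± 19.6 to 0.918 ± 0.136 CPM (-6.75 ± 0.29, adjusted p = 3.6e-16). After skp-1 RNAi the arginine kinase gene argk-1 rose 32.7-fold and the collagen genes col-73 and col-77 were 140-fold and 127-fold lower. In all 15361 genes were called after prp-19 RNAi, 9627 higher and 5734 lower, and 14066 after skp-1 RNAi, 8385 higher and 5681 lower. The median of all genes lay at 0.95 and 0.65 with TMM scaling, and RLE scaling moved it by -0.33 and -0.28, so that each change is relative to that choice. Between the RNAis 2732 genes differed, 1638 higher after prp-19 RNAi. That count was 1271 without skp-1 day 5 replicate 2, 1426 without skp-1 day 5 replicate 1, 1527 without prp-19 day 5 replicate 3 and 1707 without prp-19 day 5 replicate 2. In that comparison 11 molting genes were higher and 0 lower after prp-19 RNAi, 8 heat shock genes were higher, and 16 replication genes were lower and 1 higher.

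**Figure D3:**
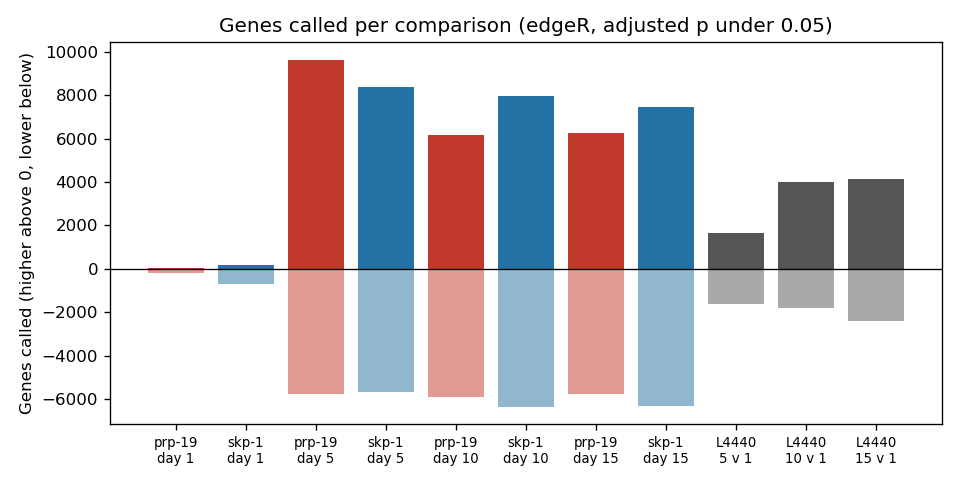
Number of genes called by edgeR (adjusted p of 0.05), higher above 0 and lower below 0, for each RNAi against L4440 at each age and for L4440 at 5, 10 and 15 days against 1 day. Counts at day 1 were 236 and 895, and at day 5 they were 15361 and 14066.

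At day 10 the libraries labelled prp-19 RNAi, in which prp-19 itself was not lower, had high sperm transcripts and low oocyte, yolk, collagen and intestinal transcripts. fer-1 was at 141 ± 15.5 against 5.62 ± 1.81 CPM (4.66 ± 0.35, adjusted p = 2.6e-11), and fog-3, which directs germ cells to sperm, was 17-fold higher (4.09 ± 0.44, adjusted p = 9.5e-09). In the sperm list 52 of 53 genes rose and 1 fell, with a median of 3.50 (camera adjusted p = 1.1e-09; adjusted p = 0.42 with an estimated correlation). Oocyte and eggshell genes fell in 31 of 34 cases with 2 rises and a median of -2.17 (camera adjusted p = 1.8e-17; adjusted p = 0.32 with an estimated correlation), chs-1 by 2.52 ± 0.19. Germline genes fell in 20 of 48 cases and rose in 7 (19 and 7 adjusted over the list alone), with a median of -0.28 and no camera call. The yolk gene vit-4 was at 4.79 ± 1.16 against 1610 ± 228 CPM (-8.40 ± 0.50, adjusted p = 7e-13), and 5 of 6 vitellogenins fell. The lysozyme gene ilys-5 was at 0.838 ± 0.153 against 505 ± 175 CPM, and the aspartyl protease gene asp-2 was 265-fold lower. Of 163 collagens 118 fell and 18 rose (121 and 18 adjusted over the list alone), with a median of -3.84 (camera adjusted p = 1e-12; adjusted p = 0.32 with an estimated correlation). col-92 had 2 counts in these libraries, a ratio of 826 (interval 228 to 6820). Part of the collagen difference is a rise in the control. The list mean was 0.55 ± 0.51 log2 CPM in L4440 at day 1, 2.67 ± 0.09 in L4440 at day 10 and -0.62 ± 0.21 in these libraries. Replicate 3 of this group held 11.52% rRNA and L4440 replicate 2 held 16.77%.

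Intestinal, muscle and metabolic lists were also lower at day 10 in these libraries. Intestine genes fell in 23 of 37 cases with 1 rise and innate immunity genes in 49 of 71 with 5 rises (50 and 6 adjusted over the list alone). Muscle genes fell in 35 of 50 cases with 3 rises, the troponin T gene tnt-2 by 5.35 ± 0.44 (adjusted p = 1.1e-10). Lipid metabolism genes fell in 48 of 82 cases and rose in 8, the fatty acid desaturase gene fat-7 by 4.42 ± 0.35 (adjusted p = 5.2e-11), and autophagy genes fell in 40 of 60 with 1 rise. Molting genes fell in 28 of 36 with 4 rises (29 and 4 adjusted over the list alone), replication genes in 40 of 50 with 0 rises and spliceosome core genes in 33 of 55 with 0 rises (median -0.41). Neuronal genes rose in 42 of 71 cases and fell in 6, with a median of 0.77. The pathogen response list had 46 risen and 2 fallen of 60, with a median of 1.65 (camera adjusted p = 6.2e-07; adjusted p = 0.32 with an estimated correlation). In all 12073 genes were called, 6170 higher and 5903 lower, and RLE scaling moved the median of all genes by 0.12.

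The libraries labelled skp-1 RNAi at day 10, in which skp-1 itself was not lower, had low germline transcripts and high neuronal ones. Germline genes fell in 46 of 48 cases with 1 rise and a median of -2.21 (camera adjusted p = 1.4e-17; adjusted p = 0.17 with an estimated correlation), and car-1 was 7.11-fold lower. Oocyte genes fell in 32 of 34 with 2 rises and a median of -3.24 (7.6e-22; adjusted p = 0.17 with an estimated correlation), and all 50 replication genes fell (2e-27; adjusted p = 0.17 with an estimated correlation). The cell cycle kinase gene cdk-1 was 7.02-fold lower and rnr-2, of deoxynucleotide synthesis, was lower as well (-3.60 ± 0.20). Sperm genes rose in 12 of 53 cases and fell in 2 (6 and 2 adjusted over the list alone). Neuronal genes rose in 62 of 71 with 2 falls and a median of 1.83 (camera adjusted p = 4.3e-09; adjusted p = 0.26 with an estimated correlation), unc-64 3.63-fold. Pathogen response genes rose in 51 of 60 with 2 falls (4.4e-09; adjusted p = 0.17 with an estimated correlation), cul-6 4.95-fold. Collagens fell in 125 of 163 with 7 rises and a median of -4.23, and rol-1 was 713-fold and col-73 1240-fold lower. The collagen list mean was -0.77 ± 0.08 log2 CPM here and 2.67 ± 0.09 in L4440 at day 10, itself above 0.55 ± 0.51 in L4440 at day 1. The saposin-like gene spp-20 rose from 2.97 ± 2.43 to 129 ± 49.1 CPM and the ferritin gene ftn-1 24.1-fold. Spliceosome core genes fell in 47 of 55 cases with 0 rises, hrpk-1 of the regulators 5.41-fold, and the RNA interference list had 42 fallen and 6 risen of 53. In all 14327 genes were called, 7971 higher and 6356 lower, with the median of all genes at 0.47, moved by -0.10 with RLE and by -0.16 with TMM without the 20 most abundant genes.

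At day 15 the libraries labelled prp-19 RNAi again had high sperm and low oocyte transcripts. fer-1 was 23.1-fold higher (4.53 ± 0.35, adjusted p = 2.8e-11), spe-41, a sperm calcium channel gene, higher by 4.02 ± 0.35 and fog-3 at 35.4 ± 5.5 against 1.22 ± 0.364 CPM. Of 53 sperm genes 49 rose and 1 fell (50 and 1 adjusted over the list alone), with a median of 2.35 (camera adjusted p = 2.8e-07; adjusted p = 0.47 with an estimated correlation). In L4440 the list level was 3.63, 3.69 and 1.07 log2 CPM in day 15 replicates 1 to 3, all below the libraries labelled prp-19 RNAi (5.58 to 5.88), and the median was 1.95 (camera adjusted p = 9e-05) without replicate 3. Oocyte genes fell in 31 of 34 with 2 rises, with a median of -2.02 (5e-16; adjusted p = 0.17 with an estimated correlation), and germline genes fell in 17 of 48 and rose in 8, with a median of -0.14 and no camera call. Muscle genes fell in 41 of 50 with 1 rise and a median of -1.66 (camera adjusted p = 7.3e-14; adjusted p = 0.17 with an estimated correlation); tnt-2 was 90.3-fold and unc-52, the perlecan of the muscle basement membrane, was lower (-4.05 ± 0.32). Collagens fell in 125 of 163 and rose in 16 (128 and 16 adjusted over the list alone), with a median of -5.29 (2e-18; adjusted p = 0.17 with an estimated correlation). col-175 had 2 counts, a ratio of 2850 (interval 789 to 23600), and col-138 had 3, a ratio of 2300 (787 to 11200). Molting genes fell in 30 of 36 with 2 rises, the hedgehog-related grd-3 263-fold. Part of both differences is a rise in the control. From day 1 to day 15 the L4440 list mean went from 0.55 ± 0.51 to 3.35 ± 0.45 log2 CPM for collagens. For molting genes it went from 1.65 ± 0.62 to 4.01 ± 0.12. In the libraries labelled prp-19 RNAi at day 15 the means were -0.93 ± 0.22 and 0.75 ± 0.21. Their collagen median against L4440 at day 1 was -1. Vitellogenins fell in 5 of 6 cases (6 adjusted over the list alone), innate immunity genes in 52 of 71 with 9 rises, intestine genes in 23 of 37 with 5 rises and lipid genes in 49 of 82 with 9 rises. Replicate 1 of the prp-19 libraries stood apart on such lists, at 8.22 log2 CPM for vitellogenins against 5.00 and 5.79, 1.86 for innate immunity against 0.18 and 0.37, and 5.71 for intestine against 3.69 and 4.02. Pathogen response genes rose in 44 of 60 with 1 fall and neuronal genes in 35 of 71 with 7 falls. In all 12031 genes were called, 6267 higher and 5764 lower, with a shift of 0.13 by RLE.

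In the libraries labelled skp-1 RNAi at day 15, where skp-1 was higher than in L4440, germline, oocyte and cell division transcripts were far below L4440. chs-1 was at 11.4 ± 1.57 against 343 ± 36.3 CPM (-4.90 ± 0.21, adjusted p = 1e-16), mex-1, a maternal RNA-binding protein gene, was 22.6-fold lower and rnr-1 lower as well (-4.01 ± 0.17). Germline genes fell in 46 of 48 with 1 rise (47 and 1 adjusted over the list alone), with a median of -2.90 (camera adjusted p = 9.2e-23; adjusted p = 0.10 with an estimated correlation). The oocyte list fell in 31 of 34 with 2 rises and a median of -4.51 (1.9e-25; adjusted p = 0.094 with an estimated correlation), and the replication list in 50 of 50, with a median of -2.98 (2e-31; adjusted p = 0.094 with an estimated correlation). Sperm genes fell in 10 of 53 and rose in 2 (4 and 2 adjusted over the list alone), with list levels of 1.22, 3.16 and 2.31 log2 CPM in replicates 1 to 3 against 3.63, 3.69 and 1.07 in L4440. The pathogen response list rose in 56 of 60 with 1 fall and a median of 3.58 (2.5e-14; adjusted p = 0.094 with an estimated correlation); its member B0507.6 was 25.5-fold higher. Neuronal genes rose in 59 of 71 with 5 falls, unc-64 6.33-fold. The chitinase-like gene chil-18 rose from 0.764 ± 0.274 to 48.3 ± 21.9 CPM, the chemoreceptor gene sri-70 68-fold, the lysozyme gene lys-3 32.8-fold and the superoxide dismutase gene sod-4 9.38-fold. Collagens fell in 126 of 163 with 14 rises, and col-92, at 39.8 ± 26.3 CPM in L4440, had 0 counts over the group, at least 1380-fold lower with the floor of 3 counts taken over the group. The collagen list mean was -0.75 ± 0.18 log2 CPM here and 3.35 ± 0.45 in L4440 at day 15, itself above 0.55 ± 0.51 in L4440 at day 1. Ribosomal protein genes fell in 63 of 77 with 3 rises. In all 13751 genes were called, 7439 higher and 6312 lower, with the median of all genes at 0.31, moved by -0.18 with TMM without the 20 most abundant genes.

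Compared with each other at day 10, libraries labelled prp-19 RNAi had higher germline genes than those labelled skp-1 RNAi in 46 of 48 cases with 0 lower, a median difference of 1.99 (camera adjusted p = 8e-23; adjusted p = 0.25 with an estimated correlation). They had higher sperm genes in 52 of 53 (2.62), lower muscle genes in 35 of 50 with 2 higher (-0.95) and lower neuronal genes in 52 of 71 with 3 higher (-1.06). At day 15 germline genes were higher in 48 of 48 (2.92; camera adjusted p = 2.9e-30; adjusted p = 0.19 with an estimated correlation), sperm genes in 53 of 53 (3.37) and oocyte genes in 30 of 34 with 1 lower (2.36). Muscle genes were lower in 45 of 50 with 1 higher (-1.35), neuronal genes in 57 of 71 with 2 higher (-1.08) and pathogen response genes in 49 of 60 with 1 higher (-1.69). The number of genes that differed was 12661 at day 10 (6346 higher after prp-19 RNAi) and 13423 at day 15 (6412 higher). RLE moved the median of all genes by 0.22 and 0.20.

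**Figure D4:**
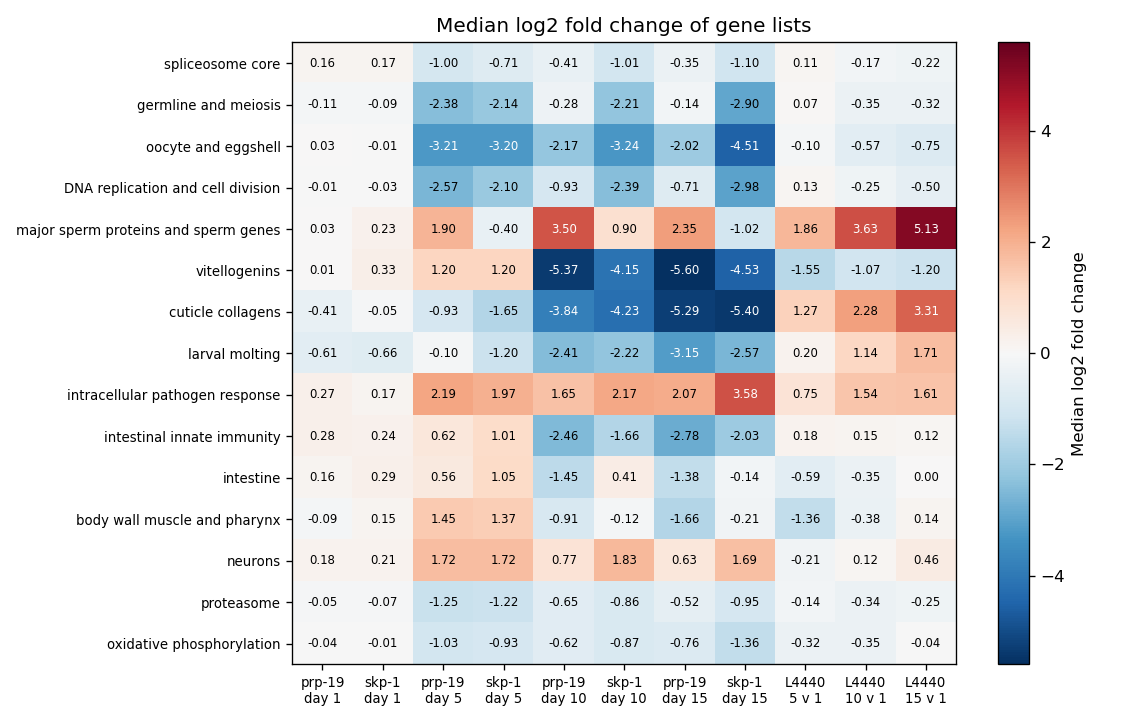
Median log2 fold change of 15 gene lists (each tested gene weighted equally) for each RNAi against L4440 at 4 ages and for L4440 at 5, 10 and 15 days against 1 day; colour gives the median. Sperm genes were at 3.50 and 2.35 for prp-19 at days 10 and 15, and oocyte genes at -2.17 and -2.02.

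Averaged over the 4 ages, collagen and oocyte genes were lower under both RNAis, with medians of -2.90 and -1.87 for prp-19 RNAi and -2.96 and -2.78 for skp-1 RNAi. Of 6 vitellogenins 4 fell under each RNAi, with medians of -2.43 (camera adjusted p = 0.0034; adjusted p = 0.44 with an estimated correlation) and -1.81 (no camera call). The collagen gene dpy-13 fell by 6.39 ± 0.37 (adjusted p = 6.2e-15) with prp-19 RNAi, and col-73 by 7.25 ± 0.50 (adjusted p = 1.1e-13) with skp-1 RNAi. The pathogen response gene pals-12 rose by 3.98 ± 0.50 (adjusted p = 5.2e-08) with prp-19 RNAi, and the F-box gene fbxa-158 by 3.32 ± 0.22 (adjusted p = 2.2e-14) with skp-1 RNAi. Of the oocyte list 31 and 32 of 34 genes fell (camera adjusted p = 1.4e-22; adjusted p = 0.18 with an estimated correlation, and 2.5e-25; adjusted p = 0.14 with an estimated correlation). In all 14800 genes were called for prp-19 RNAi, 8132 higher and 6668 lower, and 15112 for skp-1 RNAi, 8500 higher and 6612 lower. These averages join ages at which the targets were and were not lower. For collagens they also take in the rise of the list in L4440 with age.

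The RNAi effect differed with age for 14016 genes under prp-19 RNAi and 12970 under skp-1 RNAi. The genes with the smallest adjusted p included asp-2 and vit-4, near their L4440 level at day 1 (0.22 and -0.02 for prp-19) and far below it at day 10 (-8.05 and -8.40; interaction adjusted p = 1.4e-13 for each). For skp-1 RNAi they included the Argonaute gene wago-4 and chs-1 (1.6e-13 for each). Against the day 1 effect, the prp-19 effect at day 5 was more positive for 6489 genes and more negative for 5092, and at day 10 the numbers were 3218 and 4197. For skp-1 RNAi they were 6158 and 4698 at day 5 and 5060 and 5169 at day 10. Genes higher at day 5 and lower at both days 10 and 15 numbered 847 for prp-19 RNAi and 282 for skp-1 RNAi, and the reverse held for 230 and 32.

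The overlap of the RNAis was counted at each age. At day 1, 217 genes were called in the same direction (48 higher, the others lower) and 0 in opposite directions, where independent sets would share 0.633 and 6.50. That count was 57 without L4440 day 1 replicate 1, 341 without L4440 day 1 replicate 2, 84 without prp-19 day 1 replicate 2 and 86 without prp-19 day 1 replicate 3. At day 5, 12969 were shared (7720 higher, 5249 lower; 4281 and 1728 if independent) and 47 were opposite. At day 10, 9081 were shared (4571 and 4510; 2608 and 1990 if independent) and 454 were opposite, and at day 15, 8030 (3809 and 4221; 2472 and 1929) and 734. The 47 opposite genes of day 5 became 28 and 31 without L4440 day 5 replicates 1 and 3 and 78 without skp-1 day 5 replicate 3. The 454 of day 10 became 261, 301 and 279 without L4440 day 10 replicates 1, 2 and 3 and 283 without prp-19 day 10 replicate 1. The 734 of day 15 became 484 without L4440 day 15 replicate 1, 1480 without prp-19 day 15 replicate 1 and 455 without prp-19 day 15 replicate 2. The correlation of the effects across genes, which are not independent replicates, was 0.68, 0.88, 0.74 and 0.69, against 0.50, 0.50, 0.54 and 0.50 in simulations with shared controls and no effect, where at most 1 gene was shared. The covariance in fits of each age alone was 0.439, 3.003, 2.631 and 2.842, against a simulated 0.20, 0.147, 0.131 and 0.118. The 3 control libraries of an age cannot be split between the RNAis. The simulations hold no real effects, so part of the excess over independent sets can still come from shared controls. The simulated libraries were also drawn independently. At day 1 real libraries of the same place in the sample list deviated together (correlations of 0.52 to 0.80), which the simulated values leave out.

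In L4440 the lists changed with age. Against day 1, body wall muscle and pharynx genes fell at day 5 in 34 of 50 cases with 1 rise (35 and 1 adjusted over the list alone), with a median of -1.36 (camera adjusted p = 5.1e-33; adjusted p = 0.041 with an estimated correlation). The troponin gene tnt-3 went from 81 ± 12.7 to 22.2 ± 3.76 CPM (-1.86 ± 0.18, adjusted p = 8.6e-08). fmo-2 rose 57.6-fold (5.85 ± 0.57, adjusted p = 8.6e-08), the metallothionein gene mtl-1 31.3-fold and the protease gene asp-17 30.7-fold, while the collagen genes col-8 and col-119 fell 23.4-fold and 22.8-fold. Ribosomal protein genes fell in 32 of 77 cases with 0 rises (56 adjusted over the list alone), detoxification genes in 19 of 64 with 6 rises, and vitellogenins in 3 of 6, vit-3 from 3860 to 621 CPM. Collagens rose in 64 of 163 and fell in 29. In all 3273 genes were called, 1673 higher (51.1%); with RLE 64.1% of called genes were higher and with DESeq2 66.5%, RLE moving the median of all genes by 0.12. The authors' RPKM values gave 882 and 1320 genes. The autophagy list had a median of 0, a mean of -0.28 and a downward test (camera adjusted p = 0.011, or 0.8 with an estimated correlation).

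From day 10 on, sperm, collagen and molting transcripts of L4440 were above day 1. Sperm genes rose in 47 of 53 cases with 1 fall at day 10 (48 and 2 adjusted over the list alone), with a median of 3.63, or 3.56 with 1 gene at its bound (camera adjusted p = 3.6e-13; adjusted p = 0.43 with an estimated correlation). At day 15 they rose in 50 with 1 fall, with a median of 5.13, or 5.08 (1.1e-16; adjusted p = 0.35 with an estimated correlation). The mean level of the list was 3.63 and 3.69 log2 CPM in L4440 day 15 replicates 1 and 2 but 1.07 in replicate 3, beside -0.91 ± 0.16 at day 1. fer-1 rose 6.94-fold by day 10, and spe-11, a paternal-effect gene, 36.2-fold by day 15. Collagens rose in 94 of 163 with 14 falls at day 10 (102 and 18 adjusted over the list alone) and in 101 with 5 falls at day 15, with medians of 2.28 (5.5e-14; adjusted p = 0.27 with an estimated correlation) and 3.31 (2.7e-21; adjusted p = 0.16 with an estimated correlation). With 3 genes at their bound these medians were 2.23 and 3.07. The cuticle genes dpy-5 and sqt-1 were higher at day 15 than at day 1 (6.90 ± 0.74 and 6.78 ± 0.77). Molting genes rose in 19 of 36 with 1 fall and in 25 with 1 fall (2.9e-13 at day 15; adjusted p = 0.064 with an estimated correlation). Oocyte genes fell in 16 and 26 of 34, chs-1 by 0.91 ± 0.18 (adjusted p = 2e-04) by day 15. Pathogen response genes rose in 34 of 60 with 0 falls, and in 33 with 1 fall. At day 10 histone genes rose in 22 of 39 with 0 falls, at mean levels of 1.87, 1.99 and 1.49 log2 CPM in L4440 replicates 1 to 3 with rRNA shares of 5.34%, 16.77% and 1.1%. The list median of 1.32 (camera adjusted p = 7.4e-05, or 0.38 with an estimated correlation) was 1.06 without replicate 2 (camera adjusted p = 0.00022). Proteasome genes fell in 22 of 35 with 0 rises. L4440 day 10 replicate 2 held 16.77% rRNA, and the noncoding genes sup-6 and rrn-2.1, among the 5 largest rises under the rule with 48 ± 75.2 and 24400 ± 36900 CPM, lost their calls without it.

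The counts were 5798 genes at day 10 (4008 higher) and 6505 at day 15 (4120 higher). With the authors' RPKM values they were 1321 and 2710 at day 10 and 2585 and 3419 at day 15, and with own totals 3154 and 4246. At day 15 far fewer of these genes were lower than the 2385 of the main fit. The authors' RPKM values gave 2431 higher and 154 lower, and 3294 and 125, and own totals gave 3689 and 557. With only the groups compared the day 15 count was 3522. Medians and means differed in sign for the RNA interference list at day 10 (-0.21 and 0.01, test downward) and the lipid list at day 15 (-0.24 and 0.01, test downward). Neither camera call held with an estimated correlation (adjusted p = 0.44 and 0.62). Between day 5 and day 10, collagens rose in 71 of 163 with 1 fall and muscle genes in 31 of 50 with 0 falls, in a total of 3156 genes, 69.6% of them higher. That share was 36.8% with RLE (a shift of -0.17), 37.9% with DESeq2 and 88.2% without the 20 most abundant genes. The count was 1279 without L4440 day 5 replicate 1, 1398 without L4440 day 5 replicate 3, 1645 without L4440 day 10 replicate 1 and 1868 without L4440 day 10 replicate 2. Between days 10 and 15 edgeR called 2 genes: asns-1, for asparagine synthesis, rose to 10.4 ± 2.06 from 3.26 ± 0.732 CPM (1.67 ± 0.30, adjusted p = 0.04) and F15B9.6 fell to 6.43 ± 0.552 from 19.5 ± 1.17 CPM (-1.60 ± 0.25, adjusted p = 0.0078). They lie outside the rule for named genes and are named because the count was small. The day 15 libraries also carry a source name of 10 days, so the small count cannot be read as a lack of change with age. At an unadjusted p under 0.05 there were 3566 genes, and DESeq2 called 607. Without L4440 day 15 replicate 3 edgeR called 1561, without L4440 day 10 replicate 3 it called 868 and without prp-19 day 15 replicate 1 it called 126. By camera 17 lists were called between days 10 and 15, and 0 with an estimated correlation.

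**Figure D5:**
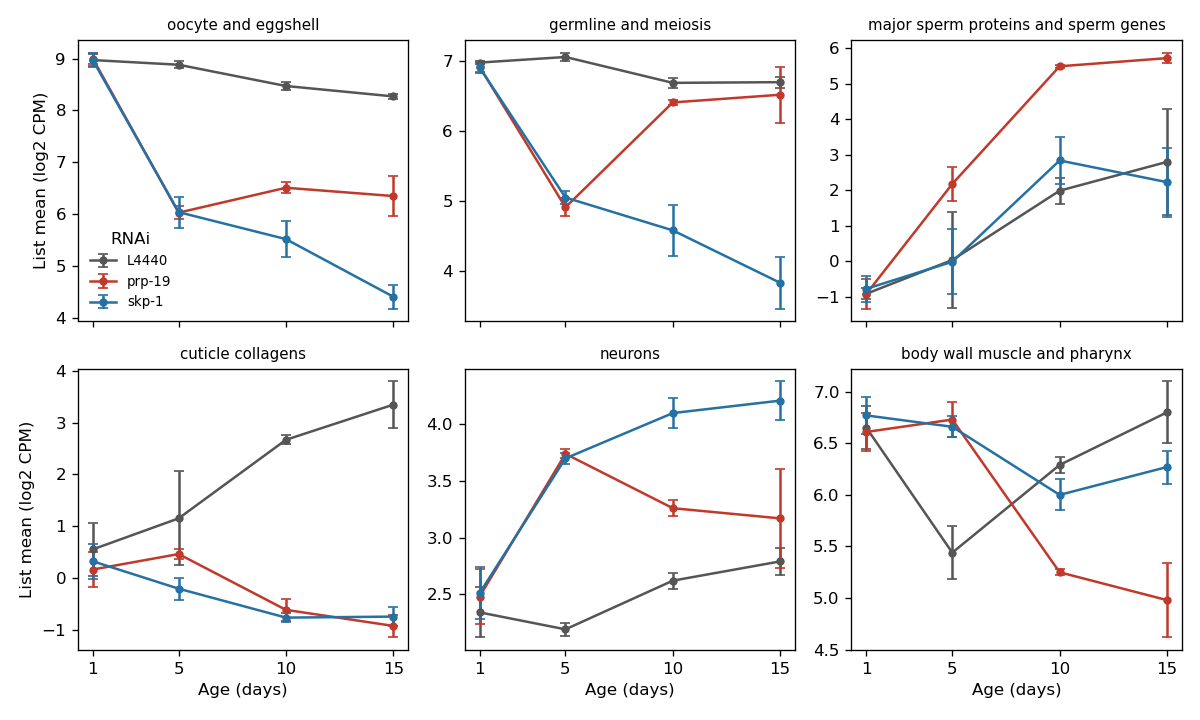
Mean log2 CPM of 6 gene lists (oocyte, germline, sperm, collagens, neurons, muscle) by age in days and RNAi condition; points are means of 3 libraries and bars 1 SD. Sperm genes rose in level from -0.91 to 2.80 in L4440 and from -0.91 to 5.72 in libraries labelled prp-19 RNAi between days 1 and 15.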

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

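Chosen only after the results were seen were the tests of larval progeny, of scaling and of sperm in place of oocytes for the prp-19 libraries, of scaling for L4440, and of genomic DNA and unspliced host transcripts for noncoding genes.

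The effect on the targeted transcripts differed between ages by a test of the difference in the edgeR model (Benjamini-Hochberg adjusted p). For prp-19 after prp-19 RNAi the log2 effect at day 10 minus that at day 1 was 2.82 (adjusted p = 4.9e-05) and at day 15 minus day 1 it was 2.14 (0.00089). For skp-1 after skp-1 RNAi the differences were 1.93 (0.0041) at day 10 and 3.75 (2e-06) at day 15. The skp-1 transcript after prp-19 RNAi differed by -1.40 (0.029) at day 5. The prp-19 transcript after skp-1 RNAi differed by -1.39 (0.015), -1.61 (0.0062) and -2.09 (0.00056) at days 5, 10 and 15. Reads of the RNAi trigger, a loss of knockdown and exchanged labels stay open, none of them tested, so values at days 10 and 15 are those of the labels. In libraries labelled skp-1 RNAi prp-19 was at 40.3% and 28.9% of L4440 at these ages and skp-1 at 102% and 360%, while in those labelled prp-19 RNAi skp-1 was at 84.9% and 98.2%, not lower as an exchange with skp-1 RNAi at full knockdown would leave it. The sperm list also ran the way of the labels, with mean levels of 2.18 and -0.01 log2 CPM in prp-19 and skp-1 RNAi libraries at day 5, 5.49 and 2.84 at day 10 and 5.72 and 2.23 at day 15. Neither the skp-1 level in libraries labelled prp-19 RNAi nor the sperm list settles the labels. The former supposes knockdown at ages where neither target was lower in its own libraries, and the latter supposes that the day 5 difference persisted. Across all genes the response differed between ages for 14016 genes with prp-19 RNAi and for 12970 with skp-1 RNAi.

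In libraries labelled prp-19 RNAi, sperm genes were higher than in L4440 at days 10 and 15 (medians 3.50 and 2.35) while oocyte genes were lower. Larval progeny would bring molting transcripts, but the molting list had a median of -3.15 at day 15 (95% bootstrap interval -4.07 to -2.38), which argues against more larvae than in L4440. The choice among 3 scalings does not account for it, since the lowest sperm median over them was 2.35. All 3 take the scale from the bulk of genes, so an error common to them was not tested. The germline list lay 1.89 above the oocyte list (1.61 to 2.27 over genes, with the spread between libraries left out). This goes with germ cells making sperm in place of oocytes. It remains a hypothesis, since in libraries labelled skp-1 RNAi the same difference was 1.61 while the sperm median was -1.02, and a difference in worm stage or sex ratio was not tested.

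In L4440, collagen, molting and sperm transcripts were higher at days 10 and 15 than at day 1. The choice among 3 scalings does not account for it, since the lowest collagen median at day 15 over them was 3.26, while an error common to all 3 was not tested. Larvae or young adults of the next generation would move the 3 lists together between libraries of an age. Over 9 L4440 libraries the deviations of collagen and molting lists from their group means had r = 0.64 (permutation p = 0.24, rho 0.57 with p = 0.25, 0.54 without the 2 farthest libraries, adjusted p = 0.36). Collagen and sperm lists had r = 0.84 (permutation p = 0.023, rho 0.85 with p = 0.023, 0.64 without those, adjusted p = 0.069) and molting and sperm lists r = 0.32 (permutation p = 0.54, rho 0.25 with p = 0.62, -0.39 without those, adjusted p = 0.54), so the lowest value, 0.32, left progeny and age impossible to separate with 9 libraries.

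At day 1 after either RNAi the median change of noncoding genes inside introns was above that of those outside coding genes, although the shares of called genes were alike. The intervals given here are over genes and leave out the spread between libraries. Genomic DNA would change genes of equal L4440 level per base alike. Against the 5 outside genes nearest in that level the median difference was 0.41 (95% bootstrap interval 0.12 to 0.65) for prp-19 RNAi and 0.75 (0.30 to 1.13) for skp-1 RNAi, which argues against it as the whole cause of the difference. Reads of unspliced host transcripts could be counted on these genes: across these genes, which are not independent replicates, the change had a Spearman rho of 0.24 (permutation p = 6e-04) with the level of the host in L4440 for prp-19 RNAi and 0.32 (permutation p = 1e-04, the smallest the permutations can give) for skp-1 RNAi. A ratio of host to nested level, tried first, had rho 0.40 and 0.46, but it shares the nested gene's own L4440 level with the change, and genes outside introns had rho -0.34 and -0.35 with that level alone. A higher yield of short RNA stays open, since snoRNA genes inside and outside introns differed by 0.59 (0 to 1.02) for prp-19 RNAi and 1.28 (-0.05 to 1.74) for skp-1 RNAi.

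Other splits of the libraries were refitted. In each comparison of 3 with 3 libraries the 10 splits are too few for a share under 0.05, and in all but 1 comparison the real split alone (1 of 10) gave as many genes. The real count and the highest of the other splits were 21 and 13 for prp-19 RNAi at day 1, and 14712, 12712 and 8694 with 0 at days 5, 10 and 15. For skp-1 RNAi they were 439 and 11 at day 1, and 13717, 14554 and 12230 with 0 at the later ages. Between the RNAis they were 87, 3043, 13491 and 10778 with 0. For L4440 they were 2527, 4406, 3522 and 2658 with 0 for days 5, 10 and 15 against 1 and 10 against 5. For L4440 at day 15 against day 10 the real count was 1 and the highest other 2001, with 2 of 10 splits as large. That split set day 15 replicates 1 and 2 with day 10 replicate 3 against the rest, so these libraries grouped otherwise than by their age labels. Whether labels were exchanged between these ages was not tested, so age is not excluded as the source of that grouping. For the averages over ages 1 of 50 splits within ages, the real one, was as large: 14608 genes with 6615 as the highest other for prp-19 RNAi, and 14887 with 1491 for skp-1 RNAi. For the interactions it was 2 of 50 for prp-19 RNAi (13668, highest other 14796) and 1 of 50 for skp-1 RNAi (12458, highest other 781). For these 4 results the share of splits as large was under 0.05. Splits with high counts mix the RNAi effect itself into both sides, so this share is no clean measure of chance. For the prp-19 interaction another split called more genes than the real one.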

How the results depend on the processing

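Chosen after seeing the data were the fits without the 2 libraries with an rRNA share above 10%, the RPKM values with own totals and a replicate block from the order of the sample list; the other alternatives were planned. The labels give no replicate numbers or pairs, so pairs by that order are a hint from the data, not the design. At day 1 libraries of the same place deviated together (correlations of 0.52 to 0.80 between groups, each library best with its own place), and at the later ages they ran from -0.49 to 0.63. Between prp-19 and skp-1 RNAi they were 0.11 to 0.53 at day 5, each library best with its own place, and 0.24 to 0.50 at day 15, with 4 of 6 best. With the block the counts at day 1 were 293 for prp-19 RNAi, 936 for skp-1 RNAi and 312 between them, and 3335 between them at day 5, no count moved by over 1.5 times, and 3 of 717 named pairs, tts-1 and col-99 after prp-19 RNAi and rbm-5 after skp-1 RNAi at day 1, lost the call. Where a count moved, the cause was not tested, except that fewer samples or genes tested are part of some alternatives.

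For prp-19 RNAi at days 5, 10 and 15, skp-1 RNAi at those ages, the averages, the interactions and the RNAis against each other at days 10 and 15, all alternatives run gave counts within 1.5 times the main one. For the 236 genes of prp-19 RNAi at day 1 the count was 107 with at least 5 CPM, 21 with only the groups compared, 49 and 29 with the authors' RPKM at pseudocounts 1 and 0.1, and 131 with own totals. For the 895 of skp-1 RNAi at day 1 it was 428, 439, 508.0 and 570 under the first 4 of these. For the 247 between the RNAis at day 1 it was 118 with at least 5 CPM and 87 with only the groups compared.

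In L4440 the authors' RPKM values at pseudocounts 1 and 0.1 gave 882 and 1320 genes for day 5 against 1 (3273), 1321 and 2710 for day 10 against 1 (5798), 2585 and 3419 for day 15 against 1 (6505) and 321 and 284.0 for day 10 against 5 (3156). Own totals gave 3154, 4246 and 1810 for the last 3. With only the groups compared, day 15 against 1 gave 3522. Day 10 against 5 gave 4866 without the 9 libraries of conflicting age, 1667 without the 2 libraries rich in rRNA and 5545 with DESeq2. Day 15 against 10 (2) gave 6 with TMM without the 20 most abundant genes, 6 with no filter, 17 with at least 5 CPM, 0 without the libraries rich in rRNA, 1 with only the groups compared, 276 and 0 with the authors' RPKM, 372 with own totals and 607 with DESeq2.

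With each library left out in turn, counts ran from 61 (without L4440 day 1 replicate 1) to 360 (without L4440 day 1 replicate 2) for prp-19 RNAi at day 1, and from 547 to 1009 (the same libraries) for skp-1 RNAi at day 1. The other libraries that moved the first were prp-19 day 1 replicates 2 (91) and 3 (92). Between the RNAis they ran from 128 (without prp-19 day 1 replicate 1; 150 without skp-1 day 1 replicate 3) to 276 at day 1 and from 1271 (without skp-1 day 5 replicate 2) to 3267 at day 5. For L4440 they ran from 1279 (without L4440 day 5 replicate 1) to 4407 (without prp-19 day 15 replicate 3) for day 10 against 5. For day 15 against 10 they ran from 0 (without L4440 day 10 replicate 2, or L4440 day 15 replicates 1 or 2) to 1561 (without L4440 day 15 replicate 3). Genes called alike by both RNAis at day 1 ran from 57 to 341 (217). Those called in opposite directions ran from 28 (without L4440 day 5 replicate 1) to 78 (without skp-1 day 5 replicate 3) at day 5 (47), from 261 to 590 at day 10 (454) and from 455 (without prp-19 day 15 replicate 2) to 1480 (without prp-19 day 15 replicate 1) at day 15 (734). The prp-19 effect at day 10 of prp-19 RNAi (0.52) ran from -0.11 (without replicate 3) to 1.00 (without replicate 2; adjusted p = 0.0067).

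Among 312 called pairs of list and comparison, 310 lost the call with an estimated correlation, 6 with RLE and 2 with TMM without the 20 most abundant genes. Leaving out libraries ended 108 of 11232 such calls, and in 2 cases the median crossed 0. For early zygotic genes after prp-19 RNAi at day 5 it ran from -0.47 (without L4440 day 5 replicate 2) to 0 (without prp-19 day 5 replicate 3; adjusted p = 0.06). For proteasome genes in L4440 at day 5 against 1 it ran from -0.25 (without L4440 day 5 replicate 3) to 0 (without prp-19 day 15 replicate 3; adjusted p = 0.15). Of the pairs of named gene and comparison, 0 changed direction in any alternative run. The call was lost for 192 with the authors' RPKM, 78 with own totals, 33 without the libraries rich in rRNA, 15 with RLE, 12 with DESeq2 and 530 of 35100 when a library was left out. Depth limits genes below 0.0665 to 0.132 CPM, where 3 counts are the floor.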

Other observations

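The family described first here was chosen after its values were seen. Of the genes called in the same direction in all 8 comparisons of an RNAi with L4440, 14 were higher and 79 lower. Among the 79, 26 belong to the fbxb family of F-box genes, of which 100 were tested (Fisher's exact test, odds ratio 123, p = 8.4e-41, on genes picked from these same data). After prp-19 RNAi, fbxb genes fell in 28 cases at day 1 with 0 rises and a median of -1.05, and in 85 at day 5 with 4 rises and a median of -3.33. After skp-1 RNAi 83 fell at day 1 with 1 rise and a median of -2.53, and 84 fell at day 5 with 5 rises and a median of -3. In libraries labelled prp-19 RNAi 86 fell at day 10 and 81 at day 15, and in those labelled skp-1 RNAi 92 and 88, with the targeted transcript not lower at these ages. In L4440 alone, against day 1, 9 rose and 9 fell at day 5 (median 0.09), 11 rose and 17 fell at day 10 (-0.31), and 1 rose and 37 fell at day 15 (-0.79). The genes resemble each other in sequence, so reads shared between members are not independent evidence.

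The sdz genes, also outside the lists as a family, fell in 4, 22, 24 and 23 of 31 cases after prp-19 RNAi at days 1, 5, 10 and 15 and in 16, 21, 25 and 26 after skp-1 RNAi. Rises numbered 0, 5, 3 and 2, and 0, 5, 2 and 3. In L4440 alone 10, 10 and 13 fell at days 5, 10 and 15 against day 1, with 4, 2 and 2 rises. Of the 79 genes lower in all comparisons, 3 were sdz, 3 btb (of 16 tested) and 3 fbxc genes (of 39 tested).

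Against L4440 at day 1, the sperm list at day 15 had a median of 7.33 in libraries labelled prp-19 RNAi (52 rose and 1 fell) and 4.06 in those labelled skp-1 RNAi (50 rose and 2 fell). The collagen list was split, with 35 rises and 76 falls of 163 and a median of -1 for prp-19 RNAi, and 36 rises and 77 falls and a median of -1.42 for skp-1 RNAi. The oocyte list had medians of -2.85 and -5.26.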
